A study of Sus scrofa with 6 samples.

How the data were processed

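Whole-genome bisulfite sequencing was done on whole pig embryos of a Landrace, Yorkshire and Duroc cross at embryonic day 21. The groups were 3 control embryos and 3 parthenotes, embryos that grow from an electrically activated egg without sperm and therefore carry maternal genomes only. Per the labels' protocols, the parthenotes developed in surrogate gilts and libraries were made with a commercial bisulfite kit. BSMAP 2.87 and the genome build Sscrofa11.1 are named in the submitters' processing notes. Trimming, removal of duplicate reads and mapping settings are not stated there.

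The deposited tables list the cytosines of CpG sites on each strand of 1 interval of chromosome 9, from position 73250031 to 75349903. The authors gave, per the file headers, the counts of reads that carry C and of reads that carry C or T at each cytosine, and the counts of opposite-strand reads that carry G and that carry G or A. They also gave an expected count, in which the C-or-T count is scaled by the opposite-strand share of G so that reads from a C-to-T sequence variant are taken off, per the file headers. The methylation fraction with its confidence interval, also deposited by the authors, is the C count over that expected count. Cytosines without a call in an embryo are listed without values. The columns for CpG island names were empty in these tables, and contexts other than CG were not listed. A planned non-CG level and a planned test of CpG islands were therefore not run, and the share of unconverted cytosines is unknown.

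The raw counts were used here, with the C or T reads as the total and both strands of a CpG summed. The total was 380163 to 406443 C-or-T reads per embryo, with a median of 27.0 to 29.0 reads per CpG. CpGs entered the single-site test with at least 10 reads in every embryo, which kept 12359 of the 14091 CpGs with a read. Windows were fixed, non-overlapping stretches of 500 bp with at least 3 CpGs and 30 reads in every embryo. Gene positions came from the RefSeq annotation of the same build, and gene strands from the promoter columns of the deposited tables. Of the 24 annotated genes in the interval, 17 had a strand there. Promoters ran from 1000 bp upstream to 500 bp downstream of the annotated gene start. They, and the exons and introns as the deposited tables annotate them, were tested with the same limits as windows.

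Methylated and unmethylated counts were compared between groups with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with a coverage term for each embryo and a group term for the methylated share. P-values were adjusted by the Benjamini-Hochberg method within each kind of unit, and an adjusted p under 0.05 counted as a call. A differentially methylated region was a run of at least 5 consecutive tested CpGs, neighbours at most 500 bp apart, each called in the same direction. Levels of single stretches were computed per embryo as methylated over total reads, except for the interval-wide level, which is the unweighted mean over CpGs. They were compared with 2-sided exact permutation tests, which with 3 against 3 embryos cannot give a p under 0.1. Intervals for single embryos are 95% Wilson intervals. They cover counting error only, and are likely too narrow even for that. The read numbers of a stretch are sums over its CpGs, so a read that spans several CpGs is counted at each. The reads also carry no molecular identifiers and are not independent molecules. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 in Python 3.11.15.

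The tests, the limits above and the rule for named items were fixed before the data were examined. By that rule every annotated gene of the interval is named, with attention to SGCE, PEG10 and their neighbours, as are up to 10 regions and the CpG with the largest difference in each of the 3 largest. The block of adjacent windows around SGCE and PEG10, its flanks and the sites singled out beside it were chosen after their values were seen. The SGCE and PEG10 promoter was planned as a CpG island and was measured over the promoter windows of the 2 genes. Alternatives fixed in advance were other coverage limits, single strands, other window and promoter sizes, other run lengths and gaps, a minimum difference, leaving out each embryo, a block on the replicate number, limma 3.58.1, DESeq2 1.42.0 and Fisher's exact test on pooled reads. Leaving out CpGs with a sign of a sequence variant, the corrected totals of the authors, centring each embryo in limma and the promoter annotation of the deposited tables were added after seeing the data. A CpG carried such a sign where, in at least 1 embryo, opposite-strand reads showed 20% or more A at 10 or more reads, or a strand had no call.

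The tests were checked on simulated counts drawn from the depth and levels of these embryos. The spread between embryos (beta-binomial rho of 0.02) was chosen and not estimated from the data. Changes were simulated as decreases at high levels and as increases at low levels, whereas all main calls in the data were increases. The recovered shares and false calls below hold for these settings only. At 12359 CpGs, edgeR recovered 27.0% of changes of 40 percentage points and 5.0% of changes of 20 points, with 0 false calls. At 1909 windows it recovered 96.0% and 44.0%, with 1 false call. Of the features, it recovered 4 of 4 changes of 40 points and 1 of 4 changes of 20 points. With no change simulated, edgeR called 0 CpGs, 0 windows and 1 feature. At most 1.58% of CpGs had equal counts in any pair of embryos, so no library was treated as a repeat of another.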

Results

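CpG methylation was measured by whole-genome bisulfite sequencing in 3 control embryos and 3 parthenotes of the pig, all whole embryos at embryonic day 21. A parthenote has no paternal genome, so a stretch of DNA that is methylated on the maternal chromosome only should read near 50% in a control and near full in a parthenote. The comparison asks where in the interval such a parent-of-origin difference lies. The tables cover 2.1 Mb of chromosome 9 (positions 73250031 to 75349903, Sscrofa11.1) around SGCE, which encodes epsilon-sarcoglycan, and PEG10, a retrotransposon-derived gene expressed from the paternal copy in mammals and needed for placental growth. Each embryo had 380163 to 406443 C-or-T reads at CpG cytosines, with a median of 27.0 to 29.0 reads per CpG. The labels count 3 embryos per group but do not say whether embryos share a litter, so embryos of a group may not be independent. The p-values set the group difference against the spread between these embryos. They cannot tell a litter difference from a group difference.

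Methylation was higher in parthenotes over a single block of 3000 bp that spans the start sites of SGCE and PEG10 (positions 74473500 to 74476499). The block level was 47.8% ± 3.41 (SD, n = 3) in controls and 95.1% ± 2.33 (SD, n = 3) in parthenotes, a difference of 47.3 percentage points. It was 45.7%, 51.8% and 46.0% in the 3 controls (95% Wilson intervals 43.6 to 47.9%, 49.6 to 53.9% and 44.0 to 48.0%). It was 92.5%, 96.0% and 96.9% in the 3 parthenotes (intervals 91.3 to 93.6%, 95.1 to 96.8% and 96.1 to 97.6%). These levels rest on 123 CpGs and 1977 to 2464 reads per embryo. The genes are transcribed away from each other from starts 217 bp apart. The block reaches 404 bp into SGCE and 2378 bp into PEG10. Of the 125 CpGs of the block with a read in any embryo, 72 lay in introns, 20 in the 5′ UTR and 1 in an exon of PEG10. Another 18 lay in the shared upstream stretch, and 6, 2 and 6 in the 5′ UTR, exons and introns of SGCE.

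The block was found by testing 1909 windows of 500 bp with edgeR. Of these, 6 were called, all higher in parthenotes, and they are the 6 adjacent windows that form the block. Control means of the 6 windows were 44.0 to 53.1% and parthenote means 92.1 to 95.8%, with adjusted p of 8.12e-08 to 2.75e-05 (edgeR). The largest difference was 51.2 percentage points in the window from 74474500 to 74474999, where the level was 44.6% ± 7.97 (SD, n = 3) in controls and 95.8% ± 2.24 (SD, n = 3) in parthenotes (630 to 950 reads per embryo, edgeR adjusted p = 8.12e-08). No window was called lower in parthenotes: edgeR found 0, against 1 lower window at an unadjusted p under 0.05, and limma, DESeq2 and Fisher's exact test on pooled reads called 0, 0 and 11. Without control 2 the number of called windows rose from 6 to 11, of which 6 were in the block.

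**Figure D1:**
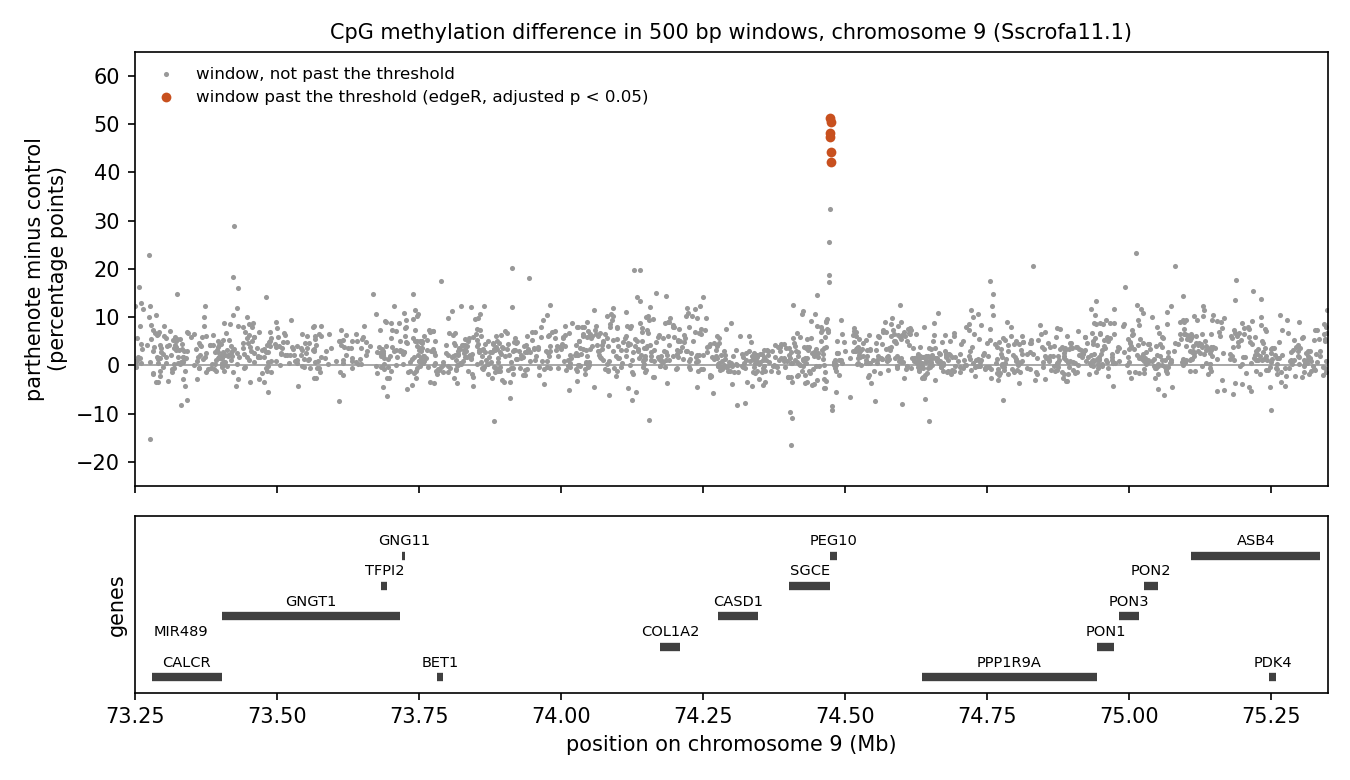
Difference in mean CpG methylation (parthenote minus control, percentage points) in each of 1909 windows of 500 bp, plotted by position on chromosome 9 (Mb), with the named genes drawn below as bars. The 6 windows called by edgeR, in orange, stand together at the start sites of SGCE and PEG10, with differences of 42.2 to 51.2 percentage points.

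The 1 differentially methylated region was a run of 32 CpGs over 634 bp (positions 74474387 to 74475020), which begins 266 bp downstream of the PEG10 start and lies wholly in intronic sequence of PEG10. The run includes the deepest part of the block and does not mark where the difference ends, since the outermost windows of the block differed by 48.1 and 50.4 percentage points at 110 to 260 reads per embryo. Its level was 46.0% ± 6.31 (SD, n = 3) in controls and 95.9% ± 2.32 (SD, n = 3) in parthenotes (909 to 1252 reads per embryo). The CpG with the largest difference in it, at position 74474948, was methylated at 41.2% ± 9.84 (SD, n = 3) in controls and 96.9% ± 0.34 (SD, n = 3) in parthenotes (29 to 54 reads, edgeR adjusted p = 0.00118). Without parthenote 2 the number of regions was 0, and without control 1 or control 3 it was 3, all inside the block. Without parthenote 3 the run was 6 CpGs long (74474734 to 74474900), and with separate strands it held 5 sites.

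In total, edgeR called 53 of 12359 CpGs, all higher in parthenotes. The block held 38 of them, and in all 63 testable CpGs of the block the parthenote mean was above the control mean. The block's CpGs had a median of 13 to 18 reads per embryo, and 62 of its 125 CpGs with a read were too shallow to test. The 15 called CpGs outside the block were isolated sites in or near GNGT1, CALCR, BET1, COL1A2, PON2, PDK4 and ASB4. Each of these 15 carried a sign of a sequence variant at the CpG, as did 437 of the 12359 tested CpGs (3.54%) and 0 of the 38 called CpGs in the block. With such CpGs left out, edgeR called 50, of which 48 were in the block and 2 outside. Chosen after its value was seen, the first of the 2, at 73499329 in an intron of GNGT1, was at 34.9% ± 29.1 (SD, n = 3) in controls and 91.2% ± 0.44 (SD, n = 3) in parthenotes (11 to 22 reads, edgeR adjusted p = 0.0456). Its levels in controls 1 to 3 were 64.7%, 6.67% and 33.3%. The nearby called CpG at 73499418, which carried a variant sign, was at 88.9%, 4.17% and 26.7% in them. Whether that variant affects the site at 73499329 was not tested. The other of the 2, chosen likewise, lay at 74472679 in an intron of SGCE and was at 24.0% ± 1.8 (SD, n = 3) against 68.7% ± 13.8 (SD, n = 3, edgeR adjusted p = 0.0372). No CpG was called lower by edgeR: the count was 0, against 37 lower among the 407 CpGs at an unadjusted p under 0.05, and limma, DESeq2 and Fisher's exact test on pooled reads called 0, 1 and 12. Among the edgeR alternatives without a replicate block, 4 CpGs were called lower without parthenote 1, 1 without parthenote 3, 1 with separate strands and 1 with the corrected totals of the authors. The count of 53 fell to 34 without control 3, to 29 without parthenote 2 and to 25 without parthenote 3, of which 25, 10 and 17 were in the block.

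The stretches beside the block differed between its SGCE and PEG10 sides. In the 1000 bp on the SGCE side (74472500 to 74473499, 35 CpGs) the level was 37.9% ± 4.96 (SD, n = 3) in controls and 66.0% ± 15.8 (SD, n = 3) in parthenotes (exact permutation p = 0.1, the smallest possible). The parthenotes were spread there, at 55.7%, 58.3% and 84.2% (95% Wilson intervals 51.0 to 60.2%, 54.0 to 62.5% and 81.2 to 86.7%, 451 to 656 reads). In the 1500 bp on the PEG10 side (74476500 to 74477999, 8 CpGs) the level was 54.8% ± 5.68 (SD, n = 3) in controls and 45.3% ± 3.04 (SD, n = 3) in parthenotes (exact permutation p = 0.1). The unweighted mean over those 8 CpGs gave an exact permutation p of 0.2. The nearest of the 8 CpGs lay between 74477000 and 74477249, so where the difference ends on the PEG10 side was not measured. These flanks were chosen after the values were seen.

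**Figure D2:**
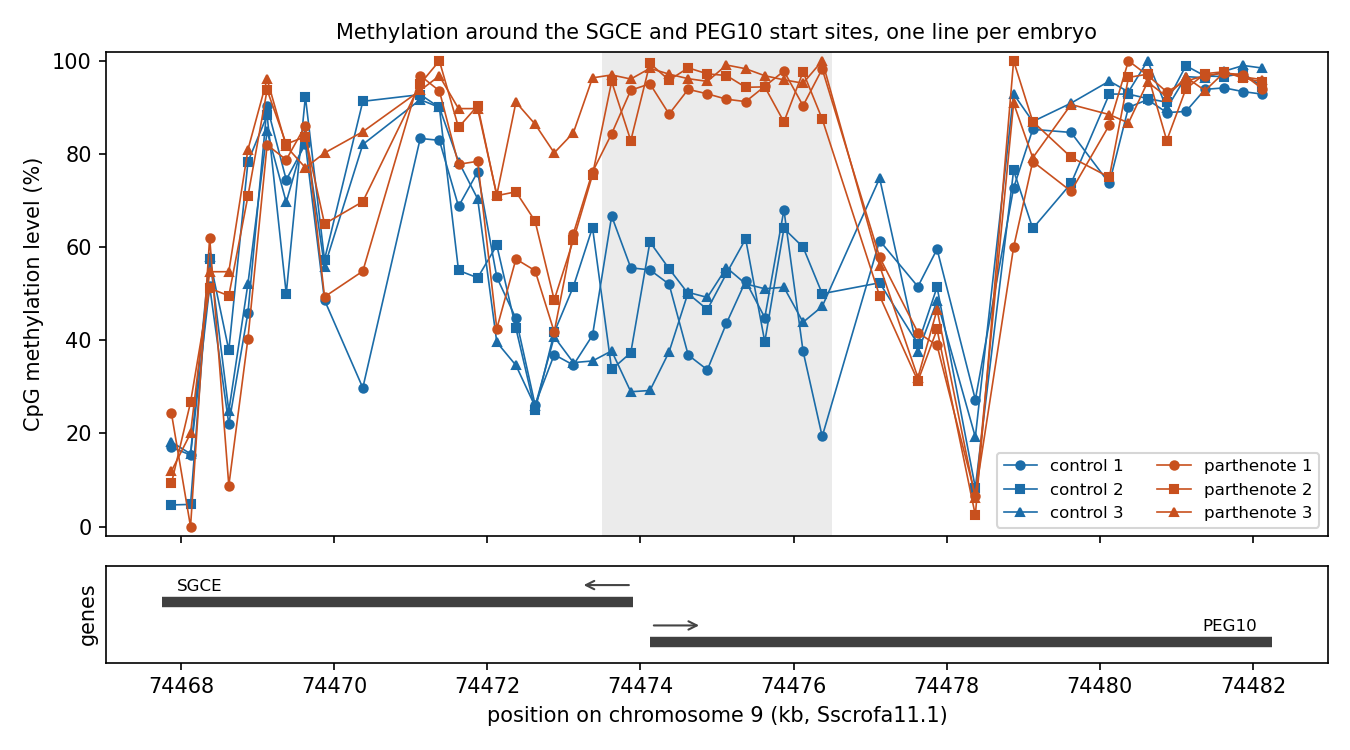
CpG methylation level (%) in 250 bp bins with at least 10 reads in every embryo, against position on chromosome 9 (kb), with 1 line per embryo (controls blue, parthenotes orange) and gene bodies with start sites and direction below. In the grey block from 74473500 to 74476499 the single bins run from 82.9 to 100% in parthenotes and from 19.4 to 68.0% in controls.

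The promoters of SGCE and PEG10 were the promoters with a called difference. Over their joint promoter stretch (74473121 to 74474904, 95 CpGs) the level was 46.1% ± 5.38 (SD, n = 3) in controls and 93.6% ± 3.12 (SD, n = 3) in parthenotes (1335 to 1566 reads per embryo). The difference of 47.5 percentage points was larger than the spread within either group, and the exact permutation p was 0.1, the smallest that 3 against 3 embryos allow. Among 48 promoters, exon sets and intron sets, edgeR called 3, all higher in parthenotes. The SGCE promoter was at 46.8% ± 4.52 (SD, n = 3) against 94.8% ± 2.9 (SD, n = 3; 83 CpGs, edgeR adjusted p = 1.33e-05). The PEG10 promoter was at 46.0% ± 8.21 (SD, n = 3) against 92.6% ± 3.66 (SD, n = 3; 82 CpGs, edgeR adjusted p = 5.97e-05). The introns of PEG10 were at 50.02% ± 3.34 (SD, n = 3) against 86.4% ± 2.0 (SD, n = 3; 88 CpGs, edgeR adjusted p = 1.33e-05). The promoters of the 2 genes share 70 CpGs, so their calls are not independent. The call of the PEG10 introns is not separate either. The same block held 72 intronic CpGs of PEG10, some of them also in the SGCE promoter. No feature was called lower by edgeR (0, with 0 at an unadjusted p under 0.05), limma or DESeq2 (0 each), while Fisher's exact test on pooled reads called 7 lower. With each embryo centred on its own median, limma called 10 features, of which 7 were lower: the promoters of BET1, MIR489, PON2 and TFPI2 and the exons of BET1, PON2 and TFPI2 (adjusted p of 0.0216 to 0.0312). The uncentred differences of these 7 were -2.11 to -6.6 percentage points, with edgeR adjusted p of 0.751 to 0.776. Their calls therefore depend on the centring.

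The exons of both genes and the introns of SGCE were not called. These sets, in which exons include the UTRs, lay mostly outside the block. It held 20 5′ UTR CpGs and 1 exon CpG of PEG10, against 199 CpGs in the exon set. For SGCE it held 6 in the 5′ UTR and 2 in exons, against 43, and 6 in introns, against 492. These comparisons therefore do not show that CpGs of these sets inside the block lack the difference. The exons of PEG10 were at 89.6% ± 3.6 (SD, n = 3) in controls and 93.6% ± 0.84 (SD, n = 3) in parthenotes (199 CpGs, edgeR adjusted p = 0.419). This comparison passed the threshold without control 2, with an edgeR adjusted p of 0.0444. The exons of SGCE were at 82.5% ± 1.85 (SD, n = 3) and 86.2% ± 2.04 (SD, n = 3), and its introns at 74.5% ± 4.64 (SD, n = 3) and 78.7% ± 1.39 (SD, n = 3; edgeR adjusted p = 0.751 for each).

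The other 15 promoters were not called, with differences of -4.9 to 9.83 percentage points and a smallest edgeR adjusted p of 0.751. Single embryos moved these limits without a call: PON1 differed by 15.3 points without parthenote 1 (edgeR adjusted p = 0.0907), ASB4 by 12.2 without control 2, and TFPI2 by -10.4 and MIR489 by -9.27 without control 1. Of these 15 promoters, 8 had levels under 25% in both groups, from 0.97 to 21.9%. They belong to CALCR, the calcitonin receptor, COL1A2, a chain of type I collagen, PDK4, a kinase that restrains pyruvate dehydrogenase, CASD1, a sialic acid O-acetyltransferase, PON2, a paraoxonase, BET1, a vesicle transport protein, and GNGT1 and GNG11, which encode G protein gamma subunits. The CALCR promoter was at 0.97% ± 0.34 (SD, n = 3) in controls and 1.04% ± 0.31 (SD, n = 3) in parthenotes, and the COL1A2 promoter at 7.62% ± 4.3 (SD, n = 3) and 7.85% ± 2.27 (SD, n = 3). Promoters at middle levels in controls included that of PPP1R9A, which encodes the actin-binding neurabin 1, at 36.3% ± 6.92 (SD, n = 3) against 37.5% ± 6.79 (SD, n = 3). The promoter of PON1, a paraoxonase of the blood, was at 46.4% ± 2.72 (SD, n = 3) against 56.2% ± 10.1 (SD, n = 3; edgeR adjusted p = 0.751). Higher levels were found at the promoters of the microRNA gene MIR489 (65.1% and 60.2%), of TFPI2, a protease inhibitor (67.3% and 62.6%), of PON3 (70.2% and 71.1%), of ASB4, an ankyrin repeat and SOCS box protein (73.1% and 80.04%), and of LOC100738575 (92.9% in both groups). In simulated data at these features edgeR recovered 1 of 4 changes of 20 percentage points, so a difference of that size at these promoters can be missed. The noncoding genes LOC106504955, LOC102163120, LOC102163402, LOC106504956, LOC106504957 and LOC106504960 and the pseudogene LOC100522026 had no strand in the tables, and their promoters were not analysed here.

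**Figure D3:**
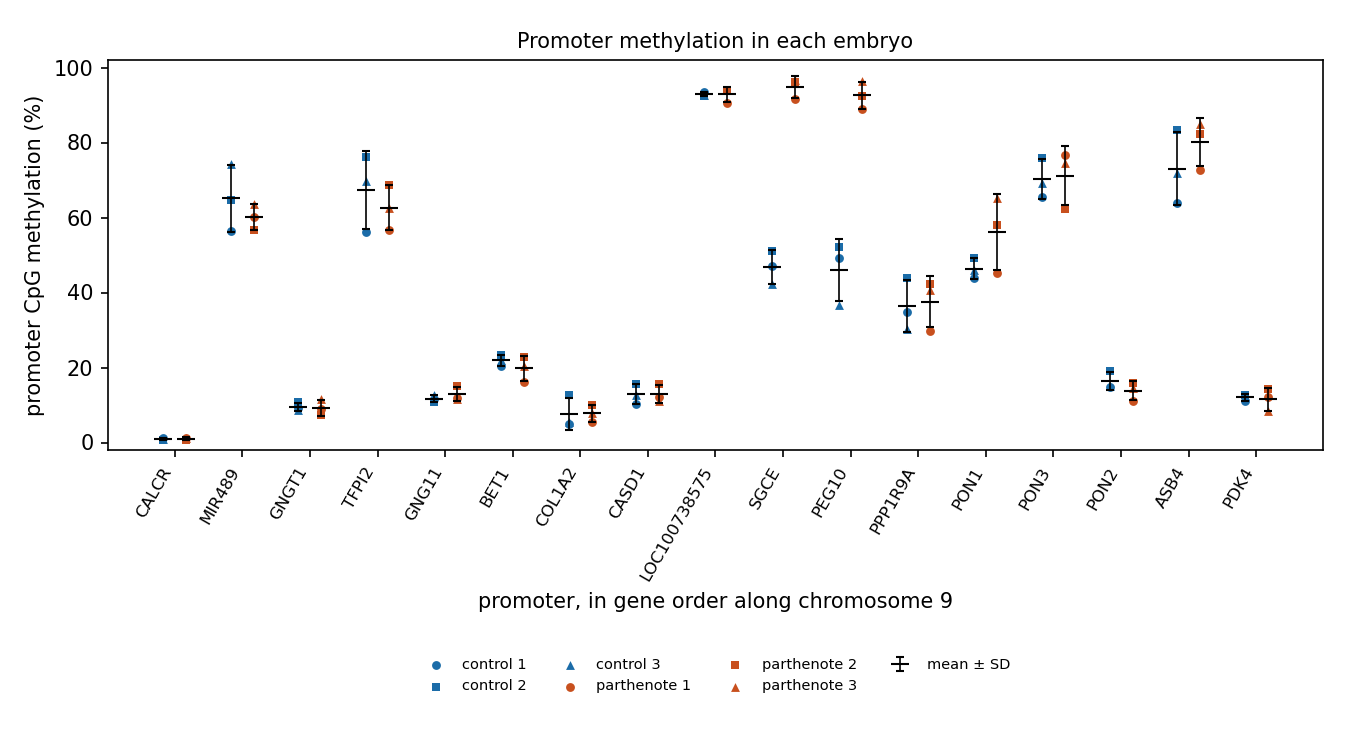
Promoter CpG methylation (%) of 17 genes in the order of their position on chromosome 9, with 1 symbol per embryo (controls blue, parthenotes orange) and bars for the mean ± SD of 3 embryos. SGCE and PEG10 stand apart, with control means of 46.8% and 46.0% and parthenote means of 94.8% and 92.6%.

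Over the whole interval, the mean methylation levels of the groups overlapped. The mean level over 12359 CpGs was 81.3% ± 5.38 (SD, n = 3) in controls and 84.3% ± 1.19 (SD, n = 3) in parthenotes, a difference of 3.01 percentage points with an exact permutation p of 0.5. Control 1 had the lowest level, 75.2%, against 83.2 to 85.6% in the other 5 embryos, and was the lowest embryo in 14 of 15 intron sets. Without control 1 the difference was -0.02 percentage points.

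Other stretches were searched for the pattern of the block, with controls at 35 to 65% and parthenotes at 80% or more. Of 123 windows at 35 to 65% in controls, 9 were at 80% or more in parthenotes and 0 at 20% or less, while 66 were at 35 to 65% in both groups. The block held 6 of the 9. The other 3 windows started at 73424500 in an intron of GNGT1 (51.7% against 80.6%), at 73914000 between BET1 and COL1A2 (60.9% against 81.1%) and at 75012500 in PON3 (62.3% against 85.7%), and edgeR called none of these 3 (adjusted p of 0.492, 0.994 and 0.6). Each of these 3 windows has 3 CpGs, of which 1, 1 and 2 carried a sign of a sequence variant. With such CpGs left out the count was 6, all in the block, but the 3 windows then fell short of the 3 CpGs needed and were not tested. At the CpGs left in them (2, 2 and 1) the levels were 61.8% against 76.6%, 64.6% against 81.0% and 93.2% against 94.1%, so that only the window at 73914000 kept the pattern, on 2 CpGs. The count depends on the limits: with 30 to 70% in controls and 75% or more, or 25% or less, in parthenotes it was 41, of which 7 lay in the block or touched it. The count of 9 was 18 without control 2 and 14 without parthenote 1.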

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

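Leaving out CpGs with a variant sign, the corrected totals, centred limma and the annotated promoter CpGs were alternatives chosen after seeing the data; the others were planned. Of 511 alternative values, 456 kept their direction and side of the threshold or, for counts, stayed near the main count. Another 13, all for uncalled features, passed the threshold under Fisher's exact test, centred limma or (PEG10 exons) without control 2. Many of the 456 are uncalled promoters that stayed uncalled. The feature tests with other coverage limits could not differ, since every feature had at least 106 reads in each embryo. For counts the tolerance was wide: 38 called sites against 53 passed as near, while 34 did not. The tally therefore does not measure how stable the calls are. The joint SGCE and PEG10 promoter difference stayed at 42.4 to 50.4 percentage points in 14 alternatives. The 6 called windows were kept in every alternative that used 500 bp windows with summed strands, except centred limma, which kept 5. Fisher's exact test on pooled reads, which ignores the spread between embryos, called 358 CpGs (12 lower), 319 windows (11 lower) and 33 features (7 lower). On simulated data, with their chosen spread between embryos, it made 62, 333 and 25 false calls. Centred limma called 10 features, 7 of them lower, against 3 and 0. Separate strands called 12 of 3189 strand windows. Windows of 250 bp gave 13 calls, 12 within 1000 bp of the block. Windows of 1000 bp gave 4 with the pattern of the block, and limits of 30 to 70% and 75% gave 41 (1 at the low end).

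With each embryo left out in turn, the called CpGs were 25 to 61, windows 6 to 11, regions 0 to 3 and windows with the pattern of the block 8 to 18, and the interval-wide difference was -0.02 to 5.09 percentage points. Uncalled promoters changed sign, with differences of -0.12 to 0.24 (CALCR), -1.23 to 1.47 (CASD1), -1.17 to 2.7 (COL1A2), -1.39 to 0.67 (GNGT1), -0.66 to 1.12 (LOC100738575), -1.95 to 1.03 (PDK4), -1.89 to 3.78 (PON3) and -1.82 to 5.13 (PPP1R9A). The shorter promoter gave -0.15 for COL1A2, 0.02 for GNGT1 and -1.12 for PPP1R9A. For these changes the cause was not tested.

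The replicate numbers did not pair the embryos: the deviations of same-numbered embryos correlated at 0.193, 0.189 and -0.281 across windows. With the replicate block, edgeR called 80 CpGs (4 lower), 8 windows, 3 features and 1 region. CpG islands and non-CG levels were not run. Depth kept 62 of the 125 CpGs of the block out of the CpG test; with no minimum beyond 1 read, 41 were called there, against 38.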

Other observations

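The tests on sequence variants at called CpGs, on mixed positions, and on other splits of the embryos were chosen only after the result was seen.

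Besides the SGCE and PEG10 block, 14 windows ranged over at least 30 percentage points within the controls and within the parthenotes. Of these, 5 lay in the 100 kb upstream of COL1A2, the type I collagen gene, and 2 more in its introns. Another 6 lay in introns of CALCR, SGCE, PPP1R9A and ASB4, and the window at 73881500 lay between BET1 and COL1A2, farther from COL1A2. In the window from 74153000 to 74153499 upstream of COL1A2 (11 CpGs, 320 to 465 reads) the levels were 25.6%, 63.0% and 18.3% in controls 1 to 3 and 9.57%, 65.6% and 62.7% in parthenotes 1 to 3. In the SGCE intron window from 74405000 to 74405499 they were 68.4%, 17.0% and 63.1% against 56.4%, 25.5% and 17.2%. In 13 of the 14 windows, control 1, control 3 and parthenote 1 lay on one side of the other 3 embryos, above them in 7 and below them in 6. These windows were picked for their range, and no explanation was tested.

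The called CpGs outside the SGCE and PEG10 block may reflect DNA sequence rather than methylation. A sign of a variant was present at 15 of the 15 called CpGs outside the block and at 0 of the 38 inside it. All of these 38 had 10 or more opposite-strand reads on each strand in a control. Fisher's exact test gave p = 1.6e-13 but treats every CpG as independent. The 38 are close neighbours in the same block, where a read can span several CpGs. That p-value therefore overstates the evidence, and only the counts are used here. The corrected totals of the authors still left 15 calls outside the block, 14 of them the same CpGs, but they rescale only the cytosine that carries the variant, not its partner on the other strand. At the 12 of the 15 CpGs where a control had no call on a strand, 3 of 474 partner-strand reads were methylated, while at other CpGs lacking a call on a strand 18.2% of 4474 were, against 83.6% where both strands had a call. The 12 CpGs had been called for low levels in controls, so a low partner-strand share follows at least in part from that choice. It is no separate support for variants. The absence of a sign at the 38 called CpGs in the block argues against variants as the source of those calls. Variants remain a candidate source of the isolated calls.

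Control 1 was less methylated than the mean of the other 5 embryos by 9.11 percentage points. The gap was 8.42 points without CpGs that carry a variant sign and 9.84 points at the 8063 CpGs with 20 or more reads in every embryo, which argues against variants and low depth as its cause. The ratio of control 1 to the other embryos was 0.867 to 0.945 in the 22 stretches of 100 kb, and its SD was 1.56 times the largest SD of another embryo, with a bootstrap interval of 0.8 to 2.51. A uniform loss of methylated reads, for example from conversion, therefore cannot be told apart from a loss that varies along the interval. The design gives no biological difference between the controls, and none was tested. Control 1 did have more cytosines with mixed bases, described below, at 14.6 per 1000 testable against 4.75 and 5.39 in controls 2 and 3. Whether this relates to its lower level was not tested.

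Mixed bases, with A in 20 to 80% of at least 10 opposite-strand reads, were rare in parthenotes: 8, 8 and 7 cytosines, against 293, 95 and 110 in the controls (0.39, 0.38 and 0.32 against 14.6, 4.75 and 5.39 per 1000 testable, exact permutation p = 0.1, the smallest possible). The parthenote with fewest testable positions had 99.9% of those of the control with most, which argues against fewer reads. Of the 377 positions mixed in a control and testable in a parthenote, 1.6% were mixed in a parthenote. With only 8, 8 and 7 mixed cytosines in the parthenotes this share had to be low. It is therefore no separate test of reads from copies elsewhere. Where an embryo showed the variant base at a position mixed in either of 2 controls other than itself, 72.7 to 82.9% of cases were mixed in the controls, but 6.6 to 30.8% in the parthenotes (9 to 61 cases per parthenote and choice of 2 controls); the rest showed the variant base alone or had no call. This is consistent with the hypothesis that the parthenotes are homozygous over most of the interval, while a litter shared by the controls, which could raise their share, was not tested.

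The real grouping gave 53 called CpGs, 6 windows, 3 features and 1 region, against at most 3, 3, 0 and 0 in any other split of the 6 embryos into groups of 3. In each case 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. The split of control 1, control 3 and parthenote 1 from the rest gave the 3 CpGs and 3 windows.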
